A study of Mus musculus with 6 samples.

How the data were processed

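Total RNA from whole brains of mouse embryos at embryonic day 18.5 was measured on 6 Affymetrix arrays, 3 from wild-type and 3 from Foxf2 mutant embryos on a C57/bl6 background. Per the labels' protocols, RNA was extracted with a Sigma mammalian total RNA kit and labelled with biotin by the Affymetrix procedure. The deposited values are MAS5 intensities on a linear scale, with MAS5 taken from the submitters' processing notes and its version not given in the sources used here. In the deposited intensity table the mean of each array without the lowest and highest 2% of probe sets lay at 100, so the authors' values were already scaled between arrays, and they were not normalized again. MAS5 signals of dim probe sets are noisy on a log scale, and scaling to a common mean hides any change in total RNA per brain. Groups and replicate numbers were taken from the labels. The labels do not say whether each array held 1 embryo or several, whether embryos shared a litter, or when arrays were run, so p-values measure the spread between these 6 samples.

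The table held 45101 probe sets, of which 64 controls were left out and 45037 were fitted. Of these, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none listed. The Entrez gene of 34741 singly named probe sets was found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. The genome build behind the array was not given in the sources used here, so no coordinates are printed and the RefSeq table served only for names and for the order of neighbouring genes. Probe sets with several genes or none are not named.

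Values were analysed as log2(value + 16) in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend), mutant minus wild type, two-sided. Fold changes are on this scale, which understates the change of dim genes. Benjamini-Hochberg adjustment covered the 27022 probe sets with a mean at or above the 40th percentile, an intensity of about 13.2, and the threshold was an adjusted p of 0.05. A gene was represented by its singly named probe set with the highest mean, which gave 18193 genes, 12573 of them above the filter. The 29 lists of pathway and cell type genes were fixed before the data were examined, as were the test, the filter and the rule for named genes. Of these lists, 28 were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, with camera at an estimated correlation and fry as alternatives. The sex-linked list was kept as values. A total of 20 list entries had no singly named probe set.

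Foxf2 was named first. Then came up to 15 genes per direction with the largest fold among probe sets past the threshold whose groups did not overlap. With fewer than 10 in a direction, the list was filled to 10 with the smallest unadjusted p and those genes are marked as not past the threshold. In each list, members past the threshold were named, otherwise the 2 members with the largest absolute fold above the filter. In the lists of vascular cells, TGF-beta and the barrier any member could be named. Gad1, past the threshold over its list alone, and Ppp1cb, B3galt2, Ddx5 and Slc25a5, for their other probe sets, were named after their values were seen.

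The fit was tested on simulated data built from the means and residual spread of the 45037 probe sets, with 200 changed probe sets in each of 5 draws. It recovered 19.6% of changes of 0.5 and 69.2% of changes of 1 on the log2 scale, and 3.04% of its calls were unchanged probe sets. The simulated endothelial list, shifted by -0.3, was called in 5 of 5 draws, with 0 calls among lists sharing no gene with it. The noise was drawn independently for each probe set, without correlation between genes or effects shared within an array. These rates may therefore be too favourable for the real arrays. Alternatives covered the offset (1 and 64), the filter (none and the 60th percentile), quantile normalization, median centring, eBayes without trend, array weights, the replicate number as a block, each array left out in turn, sex, read from Y-linked signal, as a covariate and 1 probe set per gene. Precision was limited by the number of arrays. Control ratios were compared with exact permutation tests, which cannot go below 0.1 with 3 arrays against 3.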

Results

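Transcript levels were measured in whole brains of E18.5 mouse embryos, 3 wild-type and 3 carrying a Foxf2 mutation, with 1 array per sample. Foxf2 encodes a forkhead transcription factor known from the pericytes that wrap brain capillaries, and the comparison asks which brain transcripts differ when it is mutated. The median intensity over all probe sets was 23.2 to 23.7 on the wild-type arrays and 24.4 to 25.6 on the mutant arrays. Between 41.5% and 44.0% of probe sets on each array read below an intensity of 16. Pearson correlations across tested probe sets were 0.984 to 0.989 between arrays of 1 group and 0.977 to 0.987 between arrays of different groups. The median SD of a tested probe set was 0.12 log2 units among wild-type arrays and 0.13 among mutant arrays.

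Foxf2 itself read lower in all 3 mutant brains. Its brighter probe set gave 18.6, 24.4 and 13.8 in the wild-type arrays and 8.06, 3.31 and 7.57 in the mutant arrays. The group means were 19.0 ± 5.33 (SD, n = 3) and 6.32 ± 2.61 (SD, n = 3), a log2 difference of -0.64 ± 0.15 (SE) with the offset of 16. So near the floor the offset sets this size, which was -1.49 with offset 1 and -0.24 with offset 64. The groups did not overlap, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. This probe set was too dim for the filter and so was not among those tested, and without the filter its adjusted p was 0.173. The other Foxf2 probe set read 2.02 ± 2.19 and 1.17 ± 1.39 (SD, n = 3), near the floor of the array in both groups. The labels do not describe the mutation, so it is not known whether either probe set lies in an altered part of the gene, and a probe set outside it would not check the labels.

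Itgb8 encodes the beta subunit of an integrin that activates latent TGF-beta. It was the only member of the TGF-beta, vascular cell and barrier lists past the threshold. Whole-brain RNA does not show in which cells a gene changed. The Itgb8 signal rose from 203 in wild-type to 335 in mutant brains, a log2 difference of 0.68 (adjusted p = 0.0155). It lay higher in 3 of 3 mutant arrays. The call was lost without wild-type array 1 or 2, without mutant array 2 or 3, without the variance trend and with sex as a covariate, with adjusted p over all alternatives from 0.00889 to 0.0944, while the log2 difference stayed between 0.58 and 0.72. Slco1c1 and Cldn5, genes of the blood-brain barrier, read lower without passing the threshold over all probe sets. Slco1c1, a thyroid hormone transporter of brain capillaries, went from 384 to 224 (log2 difference -0.75, adjusted p = 0.0652). Cldn5, the main claudin of endothelial tight junctions, went from 380 to 278 (log2 difference -0.43, adjusted p = 0.0622).

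**Figure D1:**
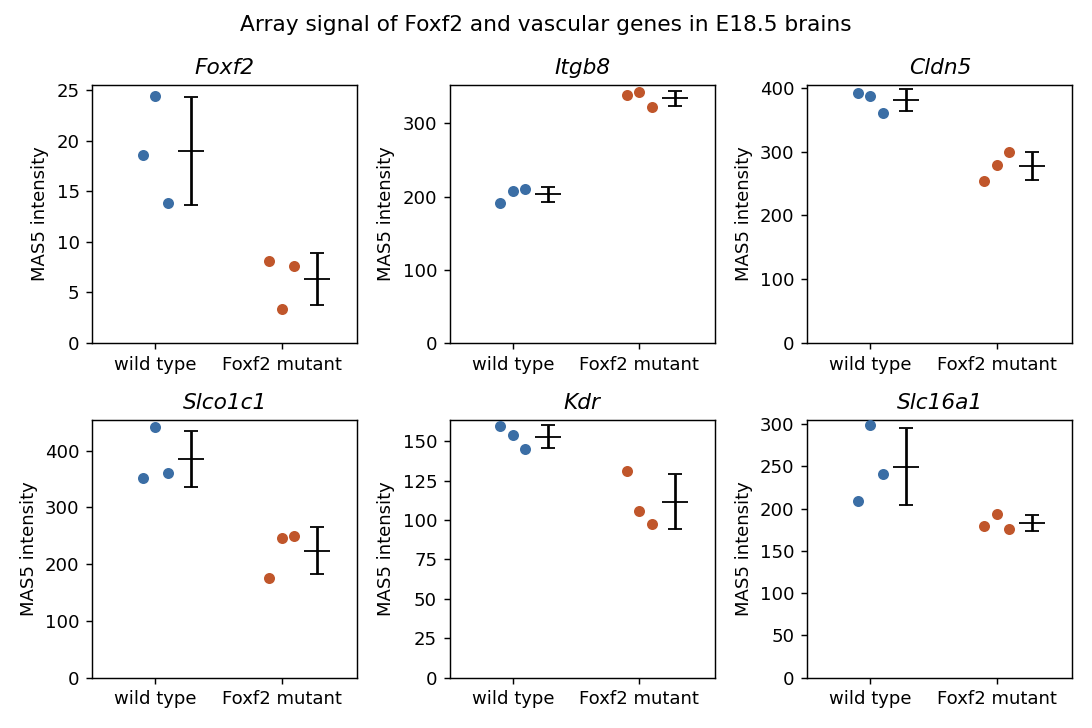
MAS5 intensity (linear axes from 0) of Foxf2 and 5 genes of the TGF-beta, endothelial and barrier lists on each array. Wild-type arrays are in blue and Foxf2 mutant arrays in orange, with black bars for mean ± SD of 3 arrays. Every mutant array lies below every wild-type array for Foxf2, Cldn5, Slco1c1, Kdr and Slc16a1, and above for Itgb8.

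Of the 25 TGF-beta and BMP signalling genes above the filter, 1 rose (Itgb8), 0 fell and 24 did not pass. Adjusted over the list alone, 2 rose, Itgb8 and Id2, an inhibitor of helix-loop-helix factors. The Id2 log2 difference was 0.52, with an adjusted p over all probe sets of 0.119, while its other probe sets had -0.21 and 0.0023. Itgav, the alpha subunit that pairs with Itgb8, had a log2 difference of 0.32 and Ltbp3, a binding protein of latent TGF-beta, of 0.46, neither past the threshold. Smad5, a mediator of BMP signals, had a difference of -0.31. The list had a median of 0.05 log2 units and did not pass camera (adjusted p = 0.692).

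Of the 18 barrier transporters and tight junction genes, 0 passed over all probe sets, and 3 fell when adjusted over the list alone: Slco1c1, Cldn5 and Slc16a1. Slc16a1, a monocarboxylate transporter, had a log2 difference of -0.40. Slc2a1, the glucose transporter of the barrier, had a difference of 0.11, Abcg2 of 0.32 and Tjp1 of 0.16. The median of the list was 0.00 and camera gave an adjusted p of 0.781. Of the 15 endothelial markers, 0 passed over all probe sets and 2 fell when adjusted over the list alone, Cldn5 and the VEGF receptor gene Kdr, whose log2 difference was -0.41. Other endothelial markers went both ways, with Tek at -0.26, Pecam1 at 0.02 and Cdh5 at 0.29. The Pecam1 difference turned to -0.03 with median centring. The endothelial list had a median of 0.00 and an adjusted p of 0.692.

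Of the 15 pericyte markers above the filter, 0 passed, also when adjusted over the list alone. Atp13a5, a pericyte ATPase gene, had a log2 difference of -0.51 on one probe set and -0.55 on another. Rgs5, a regulator of G protein signalling, had -0.33 and Pdgfrb, the PDGF receptor of pericytes, -0.25. Pericyte markers went both ways, with 6 of the 15 reading higher and 9 lower. At an unadjusted p under 0.05, 1 marker read higher and 2 lower. The median of the list was -0.05 (camera adjusted p = 0.781). Among 8 smooth muscle markers 0 passed, with Tpm2 at 0.34 and Myl9 at -0.21. Of the 16 PDGF, angiopoietin and VEGF genes 0 passed, with Kdr at -0.41 and the lymphatic growth factor Vegfc at 0.36. Among 11 permeability and caveolar genes 0 passed, with Icam2 at -0.37 and the caveolin gene Cav1 at 0.24. The 16 basement membrane genes had 0 past the threshold, with Hspg2 (perlecan) at 0.35 and the laminin gene Lamb1 at -0.27. Of the 9 endothelium and pericyte adhesion genes 0 passed, with Cdh5 at 0.29 and Ctnnd1 at -0.28.

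Over all 27022 tested probe sets, 105 differed between mutant and wild-type brains, 99 higher and 6 lower in the mutant. The higher ones named 87 genes, and their median log2 difference was 0.75, with a range of 0.34 to 1.35. Among singly named genes, the 15 with the largest folds were Gm5802, Lasp1, Ywhaz, Prdx4, Mdh1, Actr3, Wdfy1, Rab6a, Minpp1, Paics, Cnbp, Fars2, Tmem41b, Fat4 and Bcas2. Lasp1, an actin-binding protein gene, rose from 383 to 996 on a probe set of suffix _x_at (log2 difference 1.33, adjusted p = 0.0199), and Actr3, a subunit of the actin-nucleating Arp2/3 complex, from 595 to 1262. Mdh1, cytosolic malate dehydrogenase, rose from 1160 to 2618 and Ywhaz, a 14-3-3 protein gene, from 123 to 333. Wdfy1 rose from 114 to 248 (log2 difference 1.02, adjusted p = 0.0155), and Fat4, an atypical cadherin, from 151 to 305. In each of the 15, all 3 mutant arrays lay above all 3 wild-type arrays on the called probe set. The called probe sets of Gm5802, Lasp1, Mdh1, Rab6a, Minpp1, Paics, Fars2 and Bcas2 had the suffix _x_at. These rises are those of the called probe sets. Median log2 differences of the other tested probe sets were 0.01 (Ywhaz), 0.04 (Mdh1), 0.11 (Actr3), 0.21 (Wdfy1) and 0.26 (Lasp1). Fat4 had a single other tested probe set, at -0.16.

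The 5 named genes past the threshold and lower in the mutant were Rasal1, Ssr1, Cnot4, Itsn1 and Fdft1. Rasal1, a Ras GTPase-activating protein gene, fell from 23.1 to 5.96 (log2 difference -0.84, adjusted p = 0.0482). Ssr1, a translocon-associated protein gene, fell from 132 to 75.6, and Cnot4, a ubiquitin ligase of the CCR4-NOT complex, from 183 to 111. Fdft1, squalene synthase of cholesterol synthesis, fell from 1339 to 1032 (log2 difference -0.37). Itsn1, an endocytic scaffold, fell on one probe set (-0.49) and rose on another (0.90). The genes next in order, not past the threshold, were Smim27 (-1.10), the Wnt receptor gene Fzd2 (-0.74), Phax (-0.34), Cwc15 (-0.36) and Cldn5.

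Most rises were not matched by the other probe sets of the same gene. Of the 87 genes with a higher probe set, 80 had another tested probe set, and these 207 others had a median log2 difference of 0.03, with quartiles of -0.09 and 0.18. In 29 of the 80 genes another probe set read higher at an unadjusted p under 0.05, and in 12 another read lower. Of the 207 others, 41 read higher and 12 lower at this level, against 2098 and 1565 of all 27022 tested probe sets. The share reading higher was thus larger among the others than among all tested. The others held _x_at probe sets, among them the highest of Lasp1 and Mdh1, and the shares were not compared at like suffix. Fars2, which rose by 0.97 on an _x_at probe set, had -0.28 on its brighter probe set, and the single other probe set of Cnbp had -0.05. In 2 genes several probe sets passed the threshold. Ddx5, an RNA helicase gene, had 0.73 and 0.57, both on _x_at probe sets. Slc25a5, a mitochondrial ADP/ATP carrier gene, had 0.78 on a plain _at and 0.66 on an _x_at probe set. The medians of the other probe sets of Ddx5 and Slc25a5, these second ones included, were 0.19 and 0.11. The others of Lasp1 ran from -0.41 to 0.95 and those of Mdh1 from 0.012 to 0.79. The others also read higher, not past the threshold, in Ppp1cb, a protein phosphatase 1 subunit gene, with 0.55 on the called probe set and a median of 0.52 on the others, and B3galt2, a galactosyltransferase gene, with 0.83 and 0.64. Itgb8 and Gm5802 had no other tested probe set. Probe sets of suffix _x_at, whose probes can match other transcripts, made up 40.4% of the 99 and 6.02% of those tested. The mean of 3 controls for 18S ribosomal RNA was also higher on the mutant arrays, without overlap between groups. The rise was 1.20-fold on the log2 scale with the offset. Raw intensity ratios of the single 18S probe sets were 1.38, 1.32 and 1.42.

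**Figure D2:**
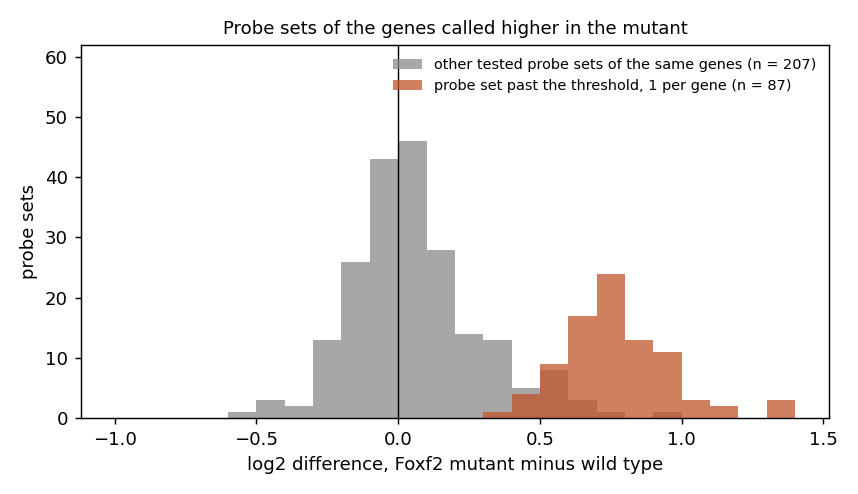
Histogram of log2 differences (mutant minus wild type, horizontal axis) for the 87 genes with a probe set called higher: the called probe set, 1 per gene, in orange and the 207 other tested probe sets of the same genes in grey, with the number of probe sets on the vertical axis. The grey distribution centres near its median of 0.03.

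At an unadjusted p under 0.05 there were 3663 probe sets, 2098 higher and 1565 lower, where chance alone gives 1351. The groups did not overlap for 20.2% of tested probe sets, where chance gives 10%. The count of 105 rested on the full set of arrays and on the variance trend: limma gave 0 without wild-type array 1 or 2, without mutant array 2 or 3 and without the trend. It gave 28 without mutant array 1, 34 without wild-type array 3 and 12 with 1 probe set per gene, among them Itgb8.

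No list passed camera: 0 of 28 at an adjusted p of 0.05, with adjusted p from 0.614 to 0.961. At an unadjusted p under 0.05 camera gave 2 lists, and with an estimated correlation it gave 0. By fry, 0 lists passed in 1 direction, 1 had an unadjusted p under 0.05, and 8 had members changing in either direction at a false discovery rate under 0.05. That mixed test does not compare a list with other genes. In 7 lists the median, mean and test differed in sign: Notch, Hedgehog, barrier, basement membrane, p53, neuron and pituitary.

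The other signalling lists had 0 members past the threshold. Of 6 neighbours of Foxf2 above the filter, Foxq1, another forkhead gene, had a log2 difference of 0.41 and Exoc2 of -0.19. Among 16 Notch genes the transcriptional mediator Rbpj had -0.31 and Notch4 0.25. Of 11 Hedgehog genes the co-receptor genes Gas1 and Cdon had -0.29 and -0.27. Of 16 Wnt genes Lef1 had -0.33 and Nkd1 0.28. Of 17 hypoxia genes Kdm3a had -0.35 and the oxygen sensor Egln1 -0.17. Of 11 haem, iron and oxidative stress genes the metallothionein gene Mt2 had 0.44 and Nqo1 0.36. Of 8 interferon and inflammatory genes 7 read higher, with a median of 0.21, Ifit3 at 0.43 and Oasl2 at 0.29; its unadjusted shift did not hold (camera adjusted p = 0.614, and adjusted p = 0.888 with an estimated correlation). Of 8 p53 genes Mdm2 had -0.25 and Ccng1 0.16. Of 9 immediate early and heat shock genes Hspa1b had -0.30 and Dusp1 -0.23, and the Hspa1b difference turned to 0.33 without wild-type array 3.

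Among markers of other brain cells, 1 of 14 astrocyte and radial glia genes rose: Vim, an intermediate filament gene, with a log2 difference of 0.45 (adjusted p = 0.0435) on an _x_at probe set. Its other probe sets had -0.03 and 0.21. Of 15 neuronal genes 0 passed over all probe sets and 1 rose when adjusted over the list alone, Gad1 with 0.31, while its other probe set had -0.21. The cortical neuron genes Tbr1 and Neurod6 had 0.36 and 0.32. Of 10 genes of dividing progenitors Ccna2 had -0.43 and Mcm2 0.42. Of 13 microglia and macrophage genes Lyz2 had 0.41 and C1qb 0.20. Of 7 oligodendrocyte genes Sox10 had 0.35 and Nkx2-2 -0.21. Of 9 choroid plexus and ependymal genes 8 read higher, with Clic6 and Rsph1 both at 0.21 (camera adjusted p = 0.614). Of 14 meningeal and fibroblast genes Foxc2 had 0.28 and Col1a1 0.26. Of 3 erythroid genes Alas2 had -0.37 and Hbb-y -0.36.

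Muscle, pituitary and sex-linked transcripts differed between single arrays. Acta1, skeletal muscle actin, read 741 in mutant array 3 and 51.1 to 77.0 in the wild-type arrays, and Myh8, a developmental muscle myosin, read 131 in mutant array 3. Gh, growth hormone of the pituitary, read 1592 in wild-type array 3 and 203 in mutant array 3, and Pomc read 202 in wild-type array 3. The log2 differences of these genes were 1.16 for Acta1, 0.99 for Myh8, -1.21 for Gh and -0.53 for Pomc, none past the threshold, and without wild-type array 3 those of Gh and Pomc turned to 0.70 and 0.17. Of 4 muscle, skin and cartilage genes and 7 pituitary and hindbrain genes above the filter, 0 passed. Xist, transcribed from the inactive X chromosome, read 1956 to 2186 in the wild-type arrays, and 1002, 13.0 and 2400 in mutant arrays 1, 2 and 3. The Y-linked Eif2s3y read 260 in mutant array 2 and at most 2.12 in the other arrays.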

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

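All tests weighed here were chosen after the result was seen, though median centring and quantile normalization were themselves set before. Means of array control families, which the comparison left out, were higher on the mutant arrays in 5 families without overlap between the groups. Single probe sets overlapped in 3 of these, 3 of 4 for bioC, 1 of 4 for bioD and 1 of 3 for 18S. The raw intensity ratio of mutant over wild type was 0.993 for 1 bioC probe set. It was 1.38, 1.32 and 1.42 for the 18S probe sets, and 1.45 and 1.14 for those of the B2 repeat. On the log2 scale with the offset, the family means gave folds of 1.20 for 18S ribosomal RNA and 1.26 for the B2 repeat. The folds were 1.07, 1.10 and 1.10 for the hybridisation spikes bioC, bioD and cre. Exact two-sided permutation tests gave p = 0.1 for each of these family means, the smallest possible. The bioB and poly-A spikes and the B1 repeat overlapped between groups. The Gapdh 3′ to 5′ ratio was 0.726 ± 0.0209 (SD, n = 3) in wild-type and 0.686 ± 0.00359 (SD, n = 3) in mutant arrays (exact permutation p = 0.1). The beta-actin ratio went the other way, from 1.28 ± 0.0361 (SD, n = 3) to 1.32 ± 0.0113 (SD, n = 3; exact permutation p = 0.2).

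The first pattern is that 99 of 105 changed probe sets were higher in the mutant. Of the 10 splits of 6 arrays into 3 and 3, only the real one gave as many calls, with at most 2 elsewhere. The 10 splits are too few for a share under 0.05, and they count calls without their direction. Array scaling bears on direction, as every mutant array had a higher median intensity than every wild-type array. Median centring left 50 higher and 6 lower, and quantile normalization gave 108 higher and 8 lower. The number of higher calls thus depended on the scaling, while most calls stayed higher under both. An effect of scaling on part of the 99 stays open. A rise of the whole transcript as large as the called rises is argued against for the 80 genes with another tested probe set as a set. The others had a median log2 difference of 0.030 and an upper quartile of 0.18, under the bound of 0.37 set from the called rises. The called probe sets were picked for passing the threshold, and the highest of each gene was kept apart from the others. Lower values in the others are thus partly built in, and a smaller rise of the whole transcript stays open for the set. Still, 41 of the 207 others read higher at an unadjusted p under 0.05, a larger share than among all tested probe sets. The shares were not compared at like suffix. The others held _x_at probe sets, among them the highest of Lasp1 (0.95) and Mdh1 (0.79), and the second called ones of Ddx5 and Slc25a5. This larger share is therefore no separate sign of whole-transcript rises. A rise of the whole transcript stays open for single genes such as Ppp1cb and B3galt2. These were picked because the median of their others reached this bound, at 0.52 and 0.64. Cross-hybridisation may account for the part on _x_at probe sets, which were over-represented with an odds ratio of 10.8 (Fisher's exact test, two-sided, p = 2.46e-23). Of all tested _x_at probe sets, 25.2% read higher at an unadjusted p under 0.05 and 3.75% lower. The test counts probe sets of the same 6 arrays as independent, so its p-value does not measure the spread between brains. It cannot separate cross-hybridisation from a run that shifts these probe sets together. A labelling or hybridisation run that differs between the groups cannot be told apart from genotype, because no run is recorded and the 18S controls differed by 0.27 log2 units. A transcript change limited to the part of a gene that 1 probe set reads, for instance another 3′ end, stays open where the other probe sets did not read higher, and genotype stays open for all 99.

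The second pattern is the lower signal of Cldn5, Slco1c1, Kdr and Slc16a1, picked after their values were seen, with a median log2 difference of -0.42. A loss of endothelial cells as large as these falls is argued against. The other 13 endothelial markers had a median of 0.020 and a lower quartile of -0.12. All 15 markers, with Cldn5 and Kdr put back, had a median of -0.002. The bound for this test, -0.21, was set from the 4 picked genes, so a smaller loss stays open. Without mutant array 2, the only array with Y-linked signal, the median of the 4 genes was -0.44. It was -0.43 without mutant array 3, with its muscle transcripts, and -0.46 without wild-type array 3, with its pituitary transcripts. The lower signal thus did not rest on any 1 of these arrays alone. In these picked genes every mutant array lay below every wild-type array, so leaving out 1 array could hardly have removed the difference. These refits therefore cannot weigh male RNA, muscle or pituitary tissue further. Genotype and an array run that differs between groups both stay open, and a lower level of these genes within endothelial cells is a hypothesis only.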

How the results depend on the processing

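The alternatives without _x_at probe sets and with plain _at probe sets only were chosen after seeing the data; the others were set before. The 105 changed probe sets became 181 with offset 1, 64 with offset 64, 52 without the filter, 167 with the filter at the 60th percentile, 56 with median centring, 12 with 1 probe set per gene, 32 without _x_at probe sets and 4 with plain _at probe sets only. They became 0 without the variance trend and 0 with sex as a covariate, where 3497 and 3224 had an unadjusted p under 0.05. As mutant array 2 was the only one with Y-linked signal, the covariate removes that array from the comparison. Leaving out 1 array at a time gave 0 to 34, with 2468 to 3910 at an unadjusted p under 0.05. Quantile normalization gave 116 and array weights 107, sharing 98 and 105 probe sets with the 105. The cause of these differences was not tested, apart from fewer arrays or probe sets in the settings built that way. The Foxf2 level stayed lower throughout, at -1.49 with offset 1 and -0.24 with offset 64. The number of lists past the threshold stayed at 0 in every setting run, and the lowest camera adjusted p was 0.0575, for muscle, skin and cartilage genes without mutant array 2.

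With the replicate number as a block the count was 220, of which 99 were among the 105. Deviations of same-numbered arrays correlated at 0.186, 0.134 and 0.0917, and each array correlated best with its own number. This is a hint of pairing from the data and not the design. The correlations are low and do not settle whether the numbers pair the arrays. The block brought 0 lists past the threshold.

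For 96 named probe sets, 28 of them past the threshold, 1717 refits gave 1432 on the same side and in the same direction, 263 no longer past it, 16 newly past it and 6 reversed. Most of the 96 were not past it at the start, and only the 28 could lose a call. Of these, 28 stayed past it with array weights and 10 without mutant array 1. None did without wild-type array 1 or 2, without mutant array 2 or 3, without the trend or with sex as a covariate. Reversed values were Pecam1 at -0.034 with median centring, and, leaving out 1 array at a time, Pecam1 from -0.097 to 0.14, Hspa1b from -0.86 to 0.33, Gh from -2.35 to 0.70 and Pomc from -0.91 to 0.17. The positive Hspa1b, Gh and Pomc values came without wild-type array 3. Cldn5 and Slco1c1 passed the threshold with offset 1 and with the filter at the 60th percentile, and Slco1c1 with the block, with adjusted p over all alternatives from 0.0443 to 0.252 and from 0.0223 to 0.236. Signal over background limits dim genes such as Foxf2.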

Other observations

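The test of the genes next to Foxf2 was written before its result was seen and its interval was added afterwards, and the rise of Fars2 on an _x_at probe set was already known.

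A hypothesis was that flanking DNA carried along with the mutated allele may shift the genes next to Foxf2. Of the 6 listed neighbours above the filter, whose values were seen earlier, 2 had an unadjusted p under 0.05, Foxq1 and Exoc2. Among the 40 nearest tested genes apart from them, 20 on each side, 10% had an unadjusted p under 0.05 (4 genes, exact binomial 95% interval 2.79% to 23.7%), against 13.5% of the 12475 other genes (Fisher's exact test, one-sided, p = 0.808). The share lay below that of the other genes, the outcome set beforehand as speaking against the hypothesis, and 0 of the 40 passed the adjusted threshold. With the listed neighbours it was 13.0%, or 6 of 46. The interval includes the share elsewhere, so the difference is within its counting error and the hypothesis stays undecided.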
